A study of Streptomyces coelicolor A3(2) with 6 samples.

How the data were processed

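The series compares 3 colony samples of *Streptomyces coelicolor* A3(2) grown under simulated microgravity with 3 grown under normal gravity. Groups and replicate numbers were taken from the source names in the labels. Per the labels' protocols, total RNA was taken from colonies at 96 h, 2 µg was reverse-transcribed and turned into cRNA, and 4 µg of cRNA was labelled with Cy3. The p-values of limma and of the t-tests measure the spread between these 3 and 3 samples, which the series' design text calls independent experiments. Those of Fisher's exact test over gene lists and of the shuffles of probe order do not measure that spread.

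Per the file headers, the intensity of each spot was extracted with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09, and the processed signal is the background-subtracted Cy3 intensity of 1 array, with no scaling between arrays. The deposited series matrix holds log2 values for the same 8116 probes. How the authors normalized them is not given in the sources used here, but every array has the same median (8.88) and the same 75th percentile (10.32). The authors' deposited table lists 196 genes with a p-value and the size of a linear fold change as a ratio, chosen per the series' design text by a t-test with p under 0.05 and a fold of at least 2. Its fold is 2 to the power of the difference between the group means of the deposited log2 values. Its positions are those of the authors' table, on the chromosome and the plasmid SCP1. Of its locus tags, 190 were found in the reference gene table of assembly ASM20383v1, which gave gene symbols for 18, and 162 had the same start and end there. Other gene symbols in the text are textbook names of the locus tags.

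From the scanner files, log2 of the processed signal minus the 75th percentile of the same array over the non-control spots was computed, so that a value of 0 is the brightness of that percentile. The 536 control spots were left out, and spots marked as non-uniform or population outliers (158 to 225 per array) were dropped after scaling. Spots of 1 probe were averaged. There were 7436 probes with 1 spot and 680 with 11, and the median SD between spots of a repeated probe was 0.100 to 0.126 log2 units per array. A probe was tested if it was well above background on at least 3 of the 6 arrays, which left 8115 and removed 1. The fit was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, neither trend nor robust), with Benjamini-Hochberg adjustment over the tested probes at 0.05, two-sided. Adjusted p of single genes in the text are limma's. With 3 samples against 3, an exact permutation test of a single value cannot go below p = 0.1. The steps were tested on simulated data with 200 of 8115 probes altered in each of 5 runs. In these simulations 48.2% of 2-fold and 88.8% of 4-fold differences were recovered at the adjusted threshold, with 7 false calls on average. At an unadjusted p under 0.05 with a fold of at least 2, 48.8% and 98.2% were recovered, with 47 false calls on average. The simulated groups had equal variance, and all 3 microgravity arrays were shifted equally. In the data the 196 listed genes had a median replicate SD of 0.57 in simulated microgravity and 0.22 in the controls. The simulated shares therefore do not carry over to such genes. Figures were drawn with matplotlib 3.10.9.

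The scanner files give probes by number, and only the 196 rows of the authors' deposited table pair a probe with a locus tag and product. The other 7920 probes are unnamed here. The unit of the tests is therefore the probe. Gene lists and product classes had been fixed before the data were examined, for a set test (camera) over all genes. That test needs names for all probes and was not run, with either a preset or an estimated correlation, and neither was fry. In its place, chosen after seeing the data, each of the 43 lists was tested for over-representation among the 196 listed genes with a one-sided Fisher's exact test, taking the full list size, 8115 tested probes as the background and Benjamini-Hochberg over the lists. The lists' genes are counted as if all had a tested probe, and listed means in the authors' deposited table. Product classes were counted with no test. Neighbours were taken in the order of probe numbers, with probes at an unadjusted p under 0.05 and a fold of at least 2 as calls, again chosen after seeing the data, and 10000 shuffles of the order.

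The rule for the genes named was also fixed before the data were examined. It took (a) the 6 higher and 6 lower genes with the largest change among those past the adjusted threshold whose groups do not overlap, (b) 4 more each way with a known product, (c) up to 4 genes with the smallest p of each list that passed its test or had at least 3 members one way, (d) 16 fixed regulators and markers, and (e) the longest run of neighbours. As none passed the threshold, (a) and (b) took the smallest unadjusted p, and (c) used the over-representation test above and the members in the authors' deposited table. Of the 16 fixed genes only sigF has a named probe.

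Alternatives fixed before the data were examined were quantile and median scaling, the 75th percentile over probes above background on all arrays, no filter and a filter on all 6 arrays, limma with trend and robust, the methods' t-test with equal variances, stricter thresholds, the deposited log2 matrix, the replicate number as a block, the slide row as a block and within row 1, strict neighbours and leaving out each sample. Added after seeing the data were normexp with an offset of 50 on the median signal, the methods' t-test with unequal variances, cyclic loess, an adjusted p under 0.10 and the unadjusted threshold with a fold of at least 2.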

Results

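*Streptomyces coelicolor* A3(2) is a soil bacterium that grows as a branching mycelium, raises aerial hyphae into the air and divides them into chains of grey spores. Colonies of the wild-type strain were grown from spores on agar at 28 °C for 96 h. The 3 simulated microgravity samples grew on a rotating clinostat, a device that keeps turning the culture so that gravity has no fixed direction, and the 3 gravity controls stayed under normal gravity on the ground. The series' design text calls the 3 samples of each group independent experiments. RNA of each sample was labelled with the dye Cy3 and hybridised to its own one-colour array, and all 6 arrays lay on 1 slide that was scanned once. Each array carried 14916 spots for 8116 probes, and between 99.97% and 99.99% of these spots were well above background. The 75th percentile of the Cy3 signal was 1234, 1236 and 1188 in control replicates 1, 2 and 3, and 1673, 1574 and 1111 in microgravity replicates 1, 2 and 3, over a median local background of 38 to 40. No spot was saturated. The number of arrays limits the precision.

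The comparison of the groups asked which genes differ in colonies kept 96 h under simulated microgravity. Signals were higher in all 3 microgravity samples than in any control for the listed genes of the whiE spore pigment cluster, the gas vesicle clusters, the chaplins and rodlins of the aerial surface, the ectoine cluster and glycogen cluster II. The mean log2 fold change of those listed genes was 2.12 for 7 whiE genes and 1.80 for 9 gas vesicle genes. It was 2.30 for 5 chaplin and rodlin genes and 2.04 for 3 ectoine genes. For 3 genes of the glycogen cluster II list, whose products are given only as hypothetical proteins, it was 1.84. Listed here means present in the authors' deposited table of 196 genes, the only table used here that gives a probe its gene. That table was chosen on these same samples and is not independent evidence of any direction. No single probe passed the adjusted threshold. Of 8115 probes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.054.

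At an unadjusted p under 0.05, 794 probes were higher and 690 lower in simulated microgravity, against 406 in all by chance. With a fold of at least 2 as well, 283 were higher and 83 lower. The methods' t-test on the same values also left 0 probes after Benjamini-Hochberg adjustment. At p under 0.05 with a fold of at least 2 it gave 253 higher and 71 lower probes with equal variances, and 170 and 43 with unequal ones. The 3 microgravity values did not overlap the 3 control values for 1996 of 8033 probes measured on all arrays, 24.8% where chance gives 10%. Of these, 955 were higher and 1041 lower, so the excess of higher probes in the counts above was absent here. The median log2 fold change over all probes was -0.001, and the median replicate SD over all probes was 0.19 in log2 units in both groups. Over the 196 genes of the authors' deposited table it was 0.57 in simulated microgravity and 0.22 in the controls, and over the 176 unnamed probes past an unadjusted p under 0.05 with a fold of at least 2 it was 0.61 and 0.18. Without simulated microgravity replicate 3, 455 probes were higher and 203 lower at an adjusted p under 0.05, as against 0 with it. Slide row was a partial batch, because row 1 held the 3 controls and microgravity replicate 1 and row 2 held microgravity replicates 2 and 3. With the row as a block, 0 probes passed the adjusted threshold, and 333 were higher and 80 lower at an unadjusted p under 0.05 with a fold of at least 2. Within row 1, 82 were higher and 20 lower at an adjusted p under 0.05, where the lone microgravity sample was assumed to vary like the controls. Row 2 held no control and gave no comparison of its own.

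The whiE cluster makes the polyketide pigment that turns spores grey. Of its 8 genes, 7 were listed in the authors' deposited table, all of them as up, where 0.193 would be listed by chance (one-sided Fisher's exact test, adjusted p = 1.45e-09 over 43 lists). They form an unbroken stretch of the chromosome from position 5785753 to 5791297 on the minus strand. The polyketide cyclase gene SCO5315 had a normalized log2 signal of 0.82 ± 0.58 (SD, n = 3) in simulated microgravity and -1.65 ± 0.27 (SD, n = 3) in the controls, a 5.53-fold difference with a limma adjusted p of 0.054. The acyl carrier protein gene SCO5316 was 6.10-fold higher, the ketosynthase subunit gene SCO5317 was 4.23-fold higher and SCO5314 was 4.81-fold higher. In the 3 microgravity samples the 7 genes lay on average 2.03, 2.76 and 1.58 log2 units above the control mean, and the controls themselves spread from -0.21 to 0.31. The other listed genes of this stretch, SCO5318, SCO5319 and SCO5320, were 2.25-fold, 2.76-fold and 7.03-fold higher.

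Gas vesicles are hollow protein shells that give buoyancy to aquatic microbes. *S. coelicolor* carries 2 clusters of such genes, and 9 of the 19 genes in them were listed in the authors' deposited table, all as up (one-sided Fisher's exact test, adjusted p = 3.76e-09). In 1 of the clusters the 7 consecutive genes SCO0649 to SCO0655, at 690966 to 694785 on the plus strand, were listed, and its remaining genes were not. SCO0650 was 5.96-fold higher, with -2.26 ± 0.29 (SD, n = 3) in the controls and 0.32 ± 0.73 (SD, n = 3) in simulated microgravity. SCO0652 was 4.05-fold and SCO0653 3.56-fold higher, and the others of these 7 lay between 2.88-fold and 4.61-fold. From the other cluster only SCO6504, 2.18-fold higher, and SCO6501, 2.25-fold higher, were listed. The limma adjusted p of these 9 genes ran from 0.054 to 0.0625. The 9 genes lay on average 1.86, 2.36 and 1.17 log2 units above the control mean in microgravity replicates 1, 2 and 3.

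Chaplins and rodlins coat aerial hyphae and spores with a water-repellent layer. Of the 11 genes in the list of chaplins, rodlins and NepA, 5 were up and none down in the authors' deposited table (one-sided Fisher's exact test, adjusted p = 4.6e-05). The rodlin genes rdlA (SCO2718) and rdlB (SCO2719) were 5.91-fold and 6.37-fold higher, and the chaplin genes chpA (SCO2716), chpD (SCO2717) and chpB (SCO7257) were 4.77-fold, 5.14-fold and 3.21-fold higher. Their limma adjusted p ran from 0.0644 to 0.0705. The rdlA signal was 4.56 ± 1.07 (SD, n = 3) in simulated microgravity and 2.00 ± 0.46 (SD, n = 3) in the controls, and without microgravity replicate 3 its log2 fold change was 3.16 in place of 2.56. As a set they lay 2.46, 3.11 and 1.34 log2 units above the control mean in microgravity replicates 1, 2 and 3.

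Ectoine is a small solute that protects cells from osmotic stress, and 3 of the 4 genes of its cluster were listed as up in the authors' deposited table (one-sided Fisher's exact test, adjusted p = 0.000469). Fold differences were 2.50 for ectA (SCO1864), 5.90 for ectB (SCO1865) and 4.71 for the ectoine synthase gene SCO1866, with limma adjusted p of 0.0621, 0.054 and 0.057. These genes were dim in the controls, and with normexp background correction the folds were 1.39, 3.58 and 2.46. Control replicate 1 lay 0.66 log2 units above the control mean for these genes, and microgravity replicates 1, 2 and 3 lay 1.95, 2.43 and 1.73 above it. Glycogen cluster II, the set of storage genes associated with sporulating aerial hyphae, had 3 of 7 genes listed as up in the authors' deposited table (one-sided Fisher's exact test, adjusted p = 0.00324). SCO7337 was 4.23-fold, SCO7336 4.32-fold and SCO7333 2.50-fold higher. The table calls the products of all 3 hypothetical proteins. When lists were counted among the probes with an unadjusted p under 0.05 and a fold of at least 2 in place of that table, the glycogen list was not over-represented without microgravity replicate 3 (adjusted p = 0.0584) or with normexp (adjusted p = 0.167), nor was the ectoine list with normexp (adjusted p = 0.0637). Unnamed probes were counted there as outside every list, which works against over-representation.

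**Figure D1:**
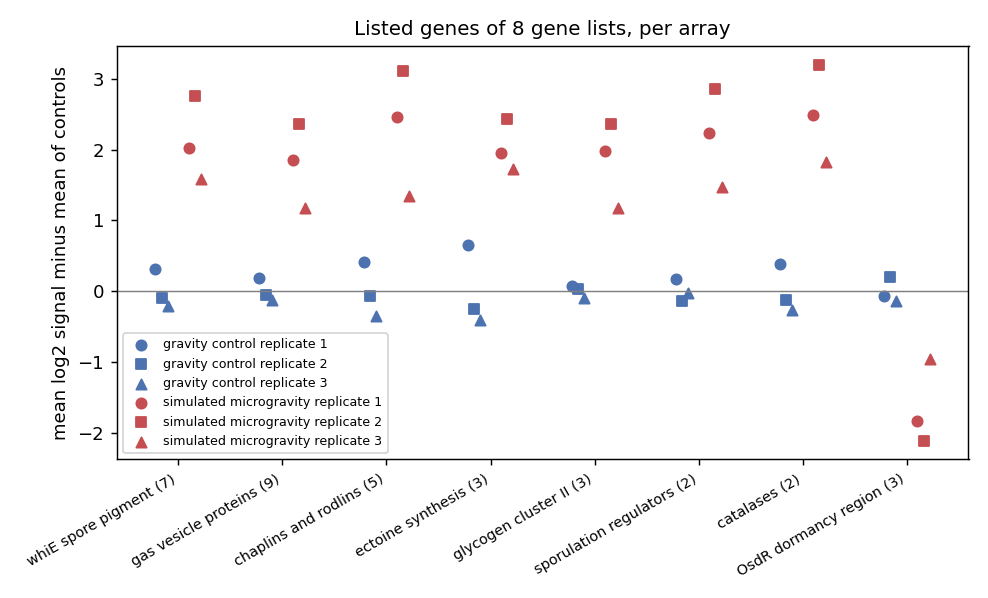
Mean log2 signal of the listed genes of 8 gene lists in each array, with the mean of the 3 controls set to 0. Blue marks are controls and red marks simulated microgravity, with the marker shape giving the replicate, and the number of listed genes stands in parentheses. The 7 whiE genes lie at 2.03, 2.76 and 1.58 in microgravity replicates 1, 2 and 3, and the 3 genes of the OsdR dormancy region lie at -1.83, -2.11 and -0.95.

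The listed genes were over-represented in 6 of the 43 lists in all. The remaining one was the left end of the chromosome, with 59 of 1500 genes in the authors' deposited table where 36.2 would be expected (one-sided Fisher's exact test, adjusted p = 0.000469), 47 of them up and 12 down. By the rule for named genes its examples were SCO0290 and SCO0935, given below, SCO0845 at 4.33-fold higher and the secreted protein gene SCO0665 at 8.22-fold higher, both with a limma adjusted p of 0.054. Among the 366 probes with an unadjusted p under 0.05 and a fold of at least 2, 59 named ones were in this list (adjusted p = 1). The 176 unnamed ones were counted as outside it, wherever they lie. That count therefore cannot show whether the left end was over-represented among those probes. The middle of the chromosome had 76 of 4300 (59 up, 17 down, adjusted p = 1) and the right end 59 of 2046 (51 up, 8 down, adjusted p = 0.262). These tests count genes, and genes of 1 operon are not independent of each other. The lists were not tested independently of that table, because no other probe carries a gene name here.

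Other lists had too few listed genes to pass. The sporulation regulators had 2 of 8 listed as up in the authors' deposited table (adjusted p = 0.0907). The late sporulation sigma factor gene sigF (SCO4035) was 5.12-fold higher, at -1.63 ± 0.61 (SD, n = 3) in simulated microgravity and -3.98 ± 0.39 (SD, n = 3) in the controls (limma adjusted p = 0.054), and the WhiB-like regulator gene whiD (SCO4767) was 4.07-fold higher. With normexp the sigF difference was 3.27-fold. Of the cell division, segregation and cell shape list 2 of 14 genes were listed as up (authors' deposited table, adjusted p = 0.188). They were sffA (SCO1416), a DNA translocase gene of the sporulation septum, at 4.34-fold and the MreB-like gene mbl (SCO2451) at 4.37-fold (2.22-fold with normexp). The SsgA-like list had only ssgG (SCO2924), at 2.79-fold (adjusted p = 0.546). Of the oxidative stress enzymes 2 of 14 were listed as up (authors' deposited table, adjusted p = 0.188), both catalases, with SCO7590 at 5.74-fold and catB (SCO0666) at 5.65-fold. The stress sigma factors had SCO7278 at 2.14-fold and SCO7314 at 2.09-fold (2 of 11 listed, adjusted p = 0.149), and the nitrate reductases had narJ (SCO6533) at 3.33-fold and 2.17-fold with normexp (1 of 12 listed, adjusted p = 0.729). The genes whiD, sffA, mbl, ssgG, catB, SCO7278, SCO7314 and narJ, and SCO6278, SCO6283 and SCO6857 elsewhere in the text, were named as the few listed members of their lists, after their values were seen. SCO6501 and rdlA were added to the 4 genes that the rule took from each of their lists.

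For antibiotic production the listed genes were few. The coelimycin cluster had 2 of 24 genes listed as up in the authors' deposited table (adjusted p = 0.406), the transport gene SCO6278 at 3.94-fold and SCO6283 at 2.57-fold. The regulator gene absR1 (SCO6992), which the list of antibiotic regulators does not hold, is given as down in that table. No gene of the actinorhodin, undecylprodigiosin, calcium-dependent antibiotic, isorenieratene, hopanoid, siderophore, coelibactin or terpene odorant lists was in that table. Nor was any of the 22 genes in the list of antibiotic regulators. The same held for the SapB ram genes, the bld genes, glycogen cluster I, ATP synthase, NADH dehydrogenase, the cytochrome bc1, aa3 and bd oxidases, the tricarboxylic acid cycle, the ribosomal protein operon, heat shock chaperones, the Pho, GlnR and Zur regulons, chitin use, arginine and histidine biosynthesis, and the SLP1 element. In all, 26 lists had no listed gene. Their absence from the authors' deposited table says only that they missed its criteria. Their probes carry no gene name here, and no value is given for them by name. As the numbers of named probes follow the chromosome, such probes might be placed between named ones. This was done only for the probes numbered 147 to 193, under the other observations.

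The authors' deposited table gives 37 genes as down and 159 as up, with a median fold of 2.25 for the former and 3.34 for the latter. By the rule for named genes, and without passing the adjusted threshold, the genes with the smallest p among the lower ones were the solute-binding protein gene SCO0290 at log2 -1.05 ± 0.13 (SE) and the GntR-family regulator genes SCO4188 at -1.19 ± 0.15 and SCO4190 at -1.12 ± 0.15. SCO4190 is devA, a regulator gene known from aerial hypha development. The unnamed probes CUST_4245_PI425740777 and CUST_4140_PI425740777 were at -1.10 ± 0.14 and -1.06 ± 0.15. A further unnamed probe is not printed. They were followed by the aminomutase gene SCO0401 at -1.10 ± 0.16, the glycosyl transferase gene SCO0398 at -1.18 ± 0.19, the secreted protein gene SCO1138 at -1.08 ± 0.21 and the dehydrogenase gene SCO5510, which was 2-fold lower. The limma adjusted p of these lower genes ran from 0.054 to 0.0625. The list of the OsdR dormancy region is named after a regulator of low-oxygen and dormancy responses. It was taken as an unbroken range of locus tags, which includes the isorenieratene list, and not as a set of that regulator's targets. Of its 54 genes 3 were listed, all down (authors' deposited table, one-sided Fisher's exact test, adjusted p = 0.467). They were SCO0207 at -1.26 ± 0.23, SCO0209 at -1.95 ± 0.35 and SCO0212 at -1.69 ± 0.37. Only named probes could enter this count, so it leaves out any unnamed probe of the region. These 3 genes lie among 47 probes numbered 147 to 193, described under the other observations. Of those, 23 were lower and 0 higher at an unadjusted p under 0.05 with a fold of at least 2. The laterally acquired island had 1 of 148 listed, SCO6857, at -1.26 ± 0.33 (adjusted p = 1).

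Among the higher genes the same rule gave SCP1.133, a gene of the linear plasmid SCP1, at log2 1.36 ± 0.13 (SE), SCO6498 at 1.67 ± 0.17 and the secreted protein gene SCO3561 at 1.89 ± 0.19. Next were the protease gene SCO6515 at 2.97 ± 0.32, SCO7451 at 2.93 ± 0.35 and the catalase gene SCO7590 at 2.52 ± 0.30. Beyond SCO5315 of the whiE cluster, the further named products were the membrane protein gene SCO6327 at 2.42 ± 0.30, the peptide transport gene SCO5119 at 1.79 ± 0.23 and the secreted protein gene SCO0935 at 2.46 ± 0.32. All of these had a limma adjusted p of 0.054 and did not pass. Several were dim, and normexp background correction gave smaller log2 values, with 0.41 for SCP1.133, 0.67 for SCO6498, 2.10 for SCO6515, 2.08 for SCO7451 and 1.61 for SCO6327. By product text, 23 of the 24 listed secreted proteins, 18 of 21 membrane proteins, 5 of 5 lipoproteins, 3 of 3 proteases and 5 of the 6 with sigma factor in their text were given as up in the authors' deposited table. That text class holds an anti-sigma factor antagonist gene, SCO7573, which is given as up and is not a sigma factor. Hypothetical proteins were 67, of which 47 were up. Oxidoreductases and dehydrogenases had 6 of 7 up, transcriptional regulators 1 of 3, polyketide synthases 2 of 2 and cytochromes P450 1 of 1. The class of transcriptional regulators leaves out listed genes whose product reads only regulator or regulatory protein. The other 9 of the 19 product classes had no listed gene.

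All 196 genes of the authors' deposited table had the same direction in the limma fit, with 3 microgravity values on one side of the 3 control values, and 190 also had a fold of at least 2 there. An adjusted p under 0.05 over all probes was reached by 0 of them and an adjusted p under 0.10 by 185. When adjusted over the list alone, 196 of 196 passed, which is not independent evidence because the study chose the list on these samples. Without simulated microgravity replicate 3, 183 of the 196 passed over all probes. The list is what the methods' t-test, in its form with unequal variances, gives on the deposited normalized values, where 196 probes met p under 0.05 with a fold of at least 2 and all 196 were the listed ones. The form with equal variances gave 289 probes, 93 of them not in the table.

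**Figure D2:**
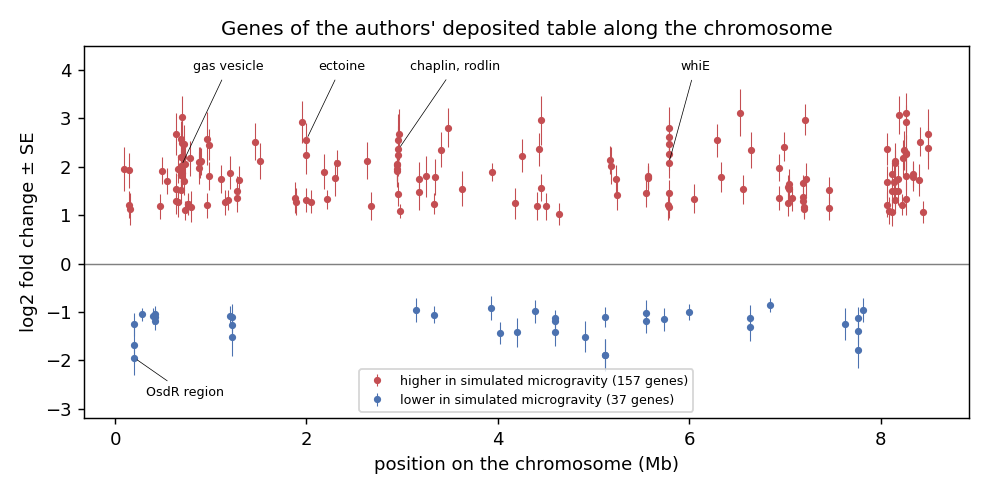
Log2 fold change of simulated microgravity over control, with its SE (n = 3 per group), for the 194 chromosomal genes of the authors' deposited table against their start position in megabases. Red points are higher and blue points lower in simulated microgravity. The gas vesicle, ectoine, chaplin and rodlin, and whiE genes stand in columns of higher points, and the lowest of the OsdR region's points is SCO0209 at -1.95.

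Probes with neighbouring numbers tended to be called together. Among the 366 probes with an unadjusted p under 0.05 and a fold of at least 2, 120 pairs of neighbours had the same direction, against a mean of 10.7 and a maximum of 25 in 10000 shuffles of the order (one-sided permutation p = 1e-04, the smallest these shuffles can give). At the adjusted threshold there were 0 such pairs, as there were 0 calls. Probe numbers stood in for the order of genes, and all 193 steps from one named chromosomal probe to the next went up the chromosome. The longest runs had 7 probes. They were the gas vesicle genes SCO0649 to SCO0655, the whiE genes SCO5314 to SCO5320, and a run of lower probes numbered 187 to 193, of which SCO0209 and SCO0212 are named. There were 49 pairs of genes with neighbouring locus tags in the authors' deposited table, and all 49 had the same direction there.

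**Figure D3:**
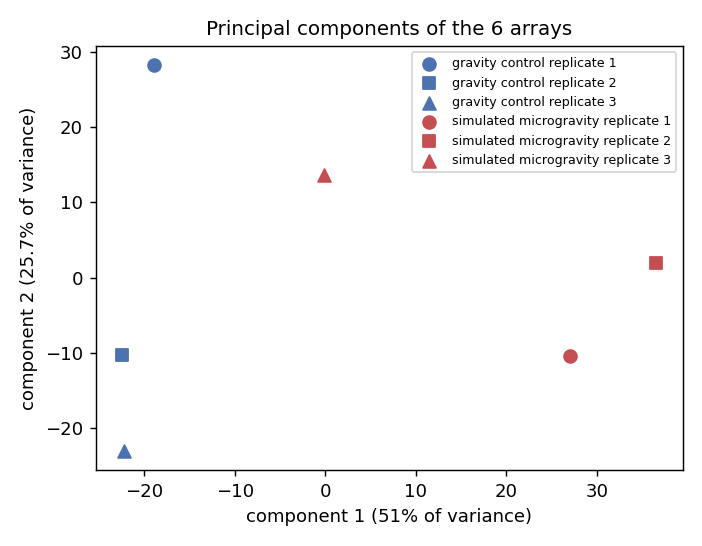
First and second principal components of the normalized log2 signals of the 6 arrays, in component score units, with the share of variance on each axis. Blue marks are controls and red marks simulated microgravity. On component 1 the controls lie from -22.4 to -18.9, microgravity replicates 1 and 2 at 27.0 and 36.5, and microgravity replicate 3 at -0.1.

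The arrays did not fall into 2 tight groups. Across probes, the correlation between arrays was 0.962 to 0.990 among the controls, 0.966 to 0.988 among the microgravity samples and 0.944 to 0.976 between the groups. Microgravity replicate 3 correlated at 0.971, 0.976 and 0.966 with control replicates 1, 2 and 3 and at 0.966 and 0.969 with microgravity replicates 1 and 2, while the latter reached at most 0.963 with any control. Component 1 held 51.0% of the variance and separated the groups, with microgravity replicate 3 between them at -0.1. Component 2 held 25.7% and ran from control replicate 1 at 28.2 to control replicate 3 at -23.0. Microgravity replicate 3 was the microgravity sample nearest to the controls in each of the first 5 gene lists above. For the 2 coelimycin genes the order differed, with 2.26 log2 units above the control mean in replicate 3 and 1.34 and 1.40 in replicates 1 and 2.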

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

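The tests with cyclic loess, normexp on the median signal, unequal variances, an adjusted p under 0.10 and the unadjusted threshold were chosen after seeing the data. All 196 listed genes kept their direction under every alternative run, and so did the 87 genes and probes followed one by one, in 1740 comparisons over 20 alternatives. That outcome was nearly fixed in advance, because all of them were chosen on these same arrays and their groups do not overlap. Leaving out a sample cannot turn such a direction, and the other tests on the same values keep the same fold. It is therefore no separate support for these directions. At the adjusted threshold median scaling gave 73 probes higher and 33 lower, with 82 listed genes passing. Cyclic loess gave 49 and 7, with 52 listed genes, and row 1 alone gave 82 and 20, with 62 listed genes. An adjusted p under 0.10 gave 305 and 191, with 185 listed genes. Leaving out 1 sample gave 0 to 455 higher and 0 to 203 lower, with 0 to 183 listed genes, and the only omission that gave any was that of microgravity replicate 3. The cause was not tested beyond the placement of that sample given under the other observations. The other alternatives left 0 at the adjusted threshold.

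At an unadjusted p under 0.05 with a fold of at least 2, normexp gave 183 higher probes, and the methods' t-test with unequal variances gave 170 higher and 43 lower. Leaving out 1 sample gave 199 to 372 higher and 63 to 129 lower. Neighbouring pairs were 78 with normexp, 58 with unequal variances and 69 to 161 when 1 sample was left out, the lowest without microgravity replicate 2. Over-represented lists among the called probes, where only the listed genes have names, so that this is no separate test, were 5 in the fit with all samples, which leaves out the left end, 3 with normexp, which lost the ectoine and glycogen lists, and 4 to 5 when 1 sample was left out, with the glycogen list lost without microgravity replicate 3. The left end was over-represented only with unequal variances (adjusted p = 0.0323). Unnamed calls were counted as outside every list in all these settings, which works against over-representation. Beyond this, the cause was not tested. With the replicate block 0 probes passed the adjusted threshold and 282 were higher and 83 lower at the unadjusted one. Whether the numbers pair the samples was not settled. Same-numbered samples' deviations from their group means correlated at -0.28, -0.17 and -0.20. Centring on a mean of 3 ties such correlations to one another, so they cannot show whether the samples were paired. Normexp on the mean signal, the brightest probe of a gene, each probe alone, camera and fry were not run, since the files lack that column or the gene names, and array weights did not converge. Dim signal limits some folds. With normexp 12 of the 87 were smaller by over 1.5 times and 14 were under 2-fold, and no other alternative made any smaller by over 1.5 times. Without microgravity replicate 2, 11 were under 2-fold.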

Other observations

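The genes named in this paragraph and the next were picked after their values were seen. None passed the adjusted threshold, and no gene group was tested here. The Dps protein genes SCO0596, SCO1050 and SCO5756, for proteins that pack and protect DNA, were 2.90-fold, 3.33-fold and 5.85-fold higher in simulated microgravity, and the histone-like protein gene hupS (SCO5556) was 2.53-fold higher. The tyrosinase gene SCO2700, for melanin, and its co-factor gene SCO2701 were 4.17-fold and 3.90-fold higher. The largest folds in the fit were those of the membrane protein gene SCO7449 and SCO5965, both at 8.69, among the 196 listed genes. SCO7449 began a run of 5 neighbours, up to SCO7453, that were all listed as up in the authors' deposited table.

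Among lower genes, hemG (SCO6041) and hemQ (SCO6042), for late steps of haem synthesis, lay at log2 -1.32 ± 0.29 (SE) and -1.12 ± 0.27, and the regulator gene absR1 (SCO6992) at -1.79 ± 0.37. SCO4688, SCO4689 and SCO4690, neighbours of unknown function, lay at -1.10, -1.89 and -1.89. The sigma factor gene SCO6996 was at -1.12 ± 0.23. For 5 unnamed probes numbered 165 to 169, the other 5 arrays lay on average 2.29 to 4.73 log2 units above control replicate 1, with an SD of at most 0.41 among themselves.

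The tests in this paragraph and those below were chosen after the results were seen. Of the 47 probes numbered 147 to 193, 23 were lower in simulated microgravity at an unadjusted p under 0.05 with a fold of at least 2, and 0 were higher. This was the stretch of probe numbers with the highest score when each lower probe counted 1 and each other probe -0.5. Its score was 11, and 3 was the highest that 1000 shuffles of the order gave (one-sided permutation p = 0.001, the smallest they can give). The median log2 fold change of the 23 probes was -2.50 and the largest difference was 9.76-fold, where the largest fold down in the authors' deposited table is 4.04. Relative to the control mean, the 23 probes had a median of -2.65, -3.53 and -1.30 in microgravity replicates 1, 2 and 3. Named among them are SCO0207, SCO0209 and SCO0212, and the other 20 are unnamed and not in that table. As all 193 steps between named chromosomal probes went up the chromosome, the numbers give a place for the unnamed ones. SCO0163, SCO0207, SCO0212 and SCO0290 are probes 143, 185, 190 and 267. If unnamed probes keep that order with 1 probe per gene, the whole stretch lies inside the list of the dormancy region. A probe annotation, which was not available here, would name the genes. Inside the stretch, the probes numbered 165 to 169 given above, with control replicate 1 far below the other 5 arrays, are not among the 23. On the same assumption about order, the probes numbered 165 to 169 would lie inside the isorenieratene list. Why the 23 were lower was not tested.

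Microgravity replicate 3 lay between the controls and the other microgravity samples. Over 500 probes called without it, on a scale with the control mean at 0 and the mean of the other microgravity samples at 1, its median placement was 0.46 (0.47 after cyclic loess), where the left-out controls had medians from -0.03 to 0.19. Against the slide row as the cause, microgravity replicate 2 in the same row had a median of 1.17 on the scale with replicate 1 at 1, where replicate 3 had 0.48. A control array under a wrong label stays open, because the placement quartiles of replicate 3, 0.31 and 0.60, overlap those of control replicate 1, 0.05 and 0.40, and it correlated at 0.966 to 0.976 with the controls and at 0.966 and 0.969 with its own group. A mixture of the 2 kinds of RNA also stays open, because 34% microgravity RNA, the share that matches the higher probes, predicts a placement of 0.25 for the lower probes, whose median was 0.46 with quartiles of 0.24 and 0.66, and a weaker response of that culture, which the design cannot separate from it, may also explain it.

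Neighbouring probe numbers were called together far above the shuffled order (permutation p = 1e-04 for 120 pairs). Spots side by side on the slide do not explain it, as the median distance between spots of consecutive numbers was 0.99 of that of shuffled numbers. Genes of 1 operon sharing a transcript may do so, which was not tested.

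There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 0 probes at the adjusted threshold, which all 10 splits equalled or exceeded, and the highest of the others gave 1. At an unadjusted p under 0.05 with a fold of at least 2 the real split gave 366 probes and the highest other 114, and for neighbouring pairs 120 and 33, so that only the real split, 1 of 10, reached either count.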
